A study of Mus musculus with 4 samples.

How the data were processed

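Total RNA from 4 cerebellum samples of male C57BL/6N mice was hybridised to Affymetrix whole-transcript arrays, 1 array per sample, per the labels' protocols. RNA was accepted above a set integrity number and was amplified and biotin-labelled with GeneChip WT kits, per the labels' protocols. The deposited values were log2 probe set summaries given to 2 decimals, made by the authors with RMA, per the submitters' processing notes. The version and settings of RMA were not given in the sources used here. The log base was not stated either and was taken as 2, the scale on which RMA works, so folds rest on that reading. No scanner files were used here, so signal over background is unknown, and a dim value is given without saying whether the transcript was detected. No scan date or batch was given in the sources used here. The number of arrays limits the precision.

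Each of the 4 value columns was matched to its sample, and samples were grouped by the title labels as vehicle (n = 2) or clothianidin (n = 2). Gene names came from a platform annotation table, which can be old, updated through gene identifiers with the RefSeq gene table of assembly GRCm38.p6, by which 0 symbols changed. Of 22206 probe sets, 19572 had 1 gene symbol, 0 had several and 2634 were not named by the table. There were 19505 symbols, 55 of them with several probe sets, where the one with the highest mean stood for the gene. A second probe set for Ddit3 had a log2 difference of -0.09 where the first had 0.54. No array positions are printed because the build behind the annotation was not given.

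The test, its alternatives, the rule for named genes and 38 lists (23 gene lists and 15 cell type lists) were fixed before the data were examined. Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all probe sets and Benjamini-Hochberg adjustment at 0.05. The prior SD was 0.306 with 5.96 prior degrees of freedom added to 2 residual ones. The median standard error of a log2 difference was 0.298, so a difference of 0.69 reached an unadjusted p of 0.05 at that error. A second count took probe sets at least 1.5-fold apart whose groups did not overlap. Lists were tested with camera from limma at a preset correlation of 0.01 over 1 probe set per gene, for lists with at least 5 measured genes, with adjustment over the 37 lists tested. The list of mitochondrially encoded genes had 0 measured members and was not analysed here. Of the listed names, Bmal1, Atp5f1 and 1500015O10Rik were matched through synonyms.

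Genes were named by a fixed rule. In each direction the rule took the 10 largest log2 differences among named probe sets at or above the median level, first those passing the adjusted threshold and then those with unadjusted limma p under 0.05. It also took up to 4 members of each list with the smallest unadjusted p, any member passing adjusted over the list alone, and all 16 measured nicotinic subunit genes. Predicted genes and clone names were left out.

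The procedure was tested on simulated data for the comparison of clothianidin with vehicle, with 200 of 22206 probe sets changed in each of 20 runs. At a log2 change of 1 it recovered 0.4% of changed probe sets, at 1.5 it recovered 10.1%, at 2 it recovered 53.5% and at 3 it recovered 95.1%, and 5.19% of calls were false. A list of 42 genes shifted by 0.25 was called in 65% of runs, and 0.139% of unshifted lists were called in these simulations, where genes vary independently. Alternatives were median centring, a further quantile normalization, filters on level at the median and the 25th percentile, 1 probe set per gene, other priors in eBayes, a linear model without moderation, other thresholds of p and fold, camera with an estimated correlation or on ranks, fry, and leaving out each array in turn.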

Results

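Gene expression was measured in the cerebellum of male C57BL/6N mice aged 10 weeks that had received the neonicotinoid insecticide clothianidin or vehicle by mouth for 4 days. Clothianidin, an agonist of insect nicotinic acetylcholine receptors, was given at 50 mg per kg per day, which the series title describes as a dose at the no-observed-adverse-effect level. The mice ran on a rotarod, a test of motor coordination, during these days, and the brains were taken directly after the test. The series comprised 4 Affymetrix arrays, 2 from the vehicle group (replicates 7 and 9) and 2 from the clothianidin group (replicates 6 and 7). The median log2 value was 6.5 and 6.54 on the vehicle arrays and 6.49 and 6.5 on the clothianidin arrays. Arrays of one group were not more alike than arrays of different groups, with Pearson's r across probe sets of 0.987 between the vehicle arrays, 0.989 between the clothianidin arrays and 0.986 to 0.989 between groups. The labels state no more than that these are separate samples, so p-values measure the spread between these samples, which may be technical.

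The comparison asked which cerebellar transcripts differ after short exposure to clothianidin. The activity-dependent transcription factor gene Npas4 (probe set TC1900000944.mm.2) had a mean of 7.42 ± 1.24 (SD, n = 2) with vehicle and 4.08 ± 0.42 (SD, n = 2) with clothianidin, a measured log2 difference of -3.34 with a standard error of 0.53. The clothianidin values lay at the level of olfactory and vomeronasal receptor probe sets, whose medians on these arrays were 4.02 and 4.19, so Npas4 was not shown to be above background there and the size of its difference is uncertain. Ttr, which encodes the thyroid hormone carrier transthyretin, was at 5.70 and 5.67 with vehicle and at 6.38 and 13.96 with clothianidin. Transcripts for calcium handling, synaptic vesicles, Purkinje cells, granule cells and the heat shock response rose as lists, by medians of 0.18 to 0.26 on the log2 scale, and oligodendrocyte transcripts fell by a median of 0.19, with limma's camera test at its preset correlation. None of these 6 list calls held with an estimated correlation, where the smallest adjusted p of any list was 0.874. In that form camera rests on the residual degrees of freedom, 2 here, so a list could hardly pass. The Purkinje list had an estimated correlation of -3e-04, below the preset one. Its unadjusted camera p still went from 0.00203 to 0.078. So the loss does not tell whether correlation among genes made these calls. Several of the 6 calls rested on 1 array. Without clothianidin replicate 6 the calcium, synaptic and granule medians were 0.09, -0.06 and 0.02, while the Purkinje and heat shock medians were 0.21 and 0.17. Without vehicle replicate 7 the oligodendrocyte median was -0.04.

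No probe set passed an adjusted p of 0.05 in limma among 22206 tested, with 0 higher and 0 lower, and the smallest adjusted p was 0.997. At an unadjusted limma p under 0.05 there were 940 probe sets, 511 higher and 429 lower with clothianidin, where chance alone would give about 1110. A linear model without moderation gave 8 calls, all probe sets whose 2 rounded values were identical within both groups. Probe sets at least 1.5-fold apart with no overlap between the groups numbered 1689, of which 897 were higher and 792 lower. The same count was 2425 when vehicle replicate 7 and clothianidin replicate 6 were set against the rest, and 1438 for vehicle replicate 7 and clothianidin replicate 7 against the rest, so the real grouping did not give the most. Groups did not overlap, whatever the size of the difference, for 30.6% of probe sets, and chance gives 33.3% for 2 arrays against 2. Leaving out clothianidin replicate 6 gave 1 call, Ttr, with a log2 difference of 8.28 and a limma adjusted p of 0.0133. That fit has a single clothianidin array, taken to vary like the 2 vehicle arrays, so the call restates the value of 13.96 on replicate 7 and does not speak for the group.

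Single-gene differences often rested on 1 array, since 64 of the 103 genes named in the text moved by over 1.5 times when 1 array was left out. Among the 20 genes named by the rule on size, all of which missed the adjusted threshold with limma adjusted p = 0.997, Ttr had the largest log2 difference, 4.49 with a standard error of 1.92. Without clothianidin replicate 7 the difference for Ttr was 0.70. The paralogs Atg2a and Atg2b, which encode lipid transfer proteins of autophagosome formation, were both higher. Atg2a was at 6.06 ± 0.22 (SD, n = 2) with vehicle and 7.5 ± 0.14 (SD, n = 2) with clothianidin, and Atg2b was at 8.01 ± 0.57 and 9.47 ± 0.21 (SD, n = 2 each). The Y-linked translation initiation factor gene Eif2s3y was at 9.87 ± 0.16 and 11.28 ± 0.19 (SD, n = 2 each), a log2 difference of 1.41. The log2 difference was 1.41 for Fat1, an atypical cadherin gene, 1.40 for Mark4, a microtubule affinity-regulating kinase gene, and 1.39 for Mical2, which encodes an actin-oxidising enzyme. Leng8, Pisd-ps3 and Pdcd5 had log2 differences of 1.45, 1.41 and 1.38 with larger spread, since Leng8 was at 12.40 and 10.72, Pisd-ps3 at 14.95 and 13.26, and Pdcd5 at 11.03 and 12.41 on the clothianidin arrays.

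On the lower side, Rras2, a Ras-related GTPase gene, had a log2 difference of -1.61, with 9.77 and 10.24 on the vehicle arrays and 7.48 and 9.31 on the clothianidin arrays. Cnot6l, which encodes a deadenylase of the CCR4-NOT complex, was at 13.71 ± 0.37 with vehicle and 12.17 ± 0.73 with clothianidin (SD, n = 2 each). Foxn2, a forkhead transcription factor gene, was at 13.72 ± 0.23 and 12.57 ± 0.02, and Rbm19, an RNA-binding protein gene, was at 8.61 ± 0.01 and 7.54 ± 0.11 (SD, n = 2 each). The log2 difference was -1.43 for Tmem241, -1.27 for the ceramidase gene Acer3, -1.16 for the lipoprotein lipase gene Lpl and -1.14 for the mismatch repair gene Pms1. Without clothianidin replicate 6 it was -0.36 for Acer3 and -0.44 for Pms1, and without vehicle replicate 9 it was -0.53 for Lpl. The histone genes H4c3 and H1f3 had log2 differences of -1.11 and -1.11.

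**Figure D1:**
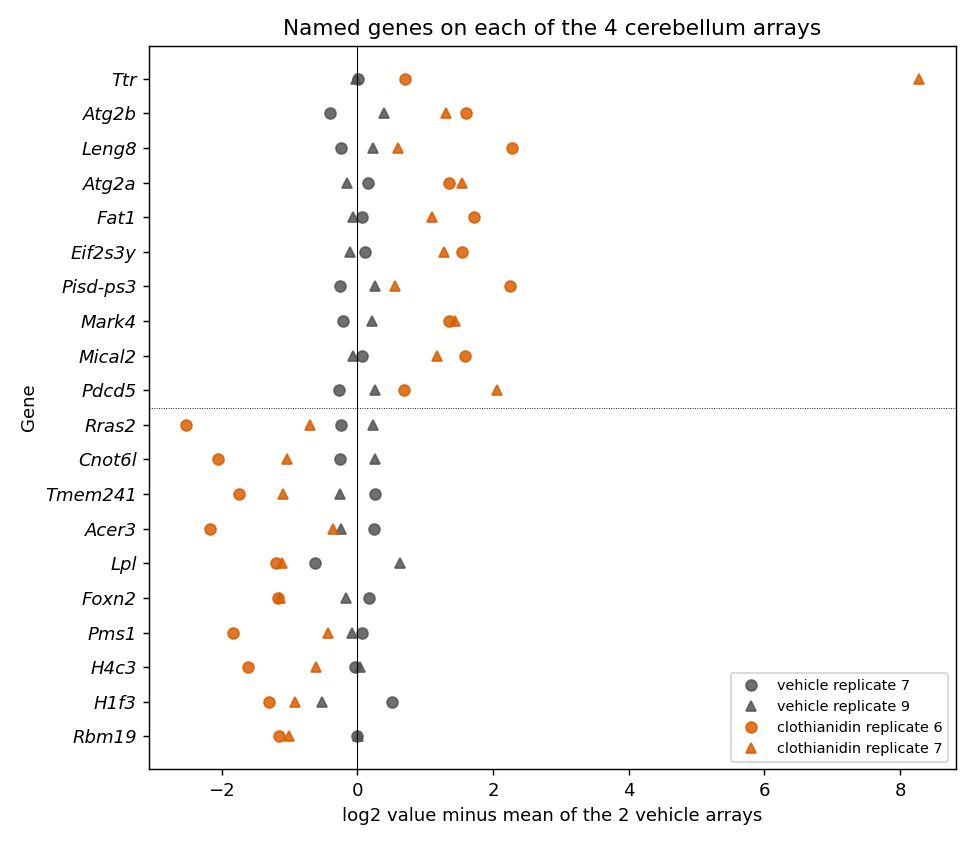
Values of the 20 genes named by size on each array, as the log2 value minus the mean of the 2 vehicle arrays. Grey points are vehicle and orange points clothianidin arrays, and the dotted line parts the higher from the lower genes. Ttr stands at 13.96 on clothianidin replicate 7 and at 6.38 on replicate 6.

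Nicotinic acetylcholine receptors are the class of target that gives neonicotinoids their name. Of the list of 24 measured subunit and chaperone genes, 9 were higher and 15 lower with clothianidin, with a median log2 difference of -0.09 (camera adjusted p = 0.326), and 0 passed limma either over all genes or adjusted over the list alone. Chrna4 and Chrnb2, which form the main heteromeric receptor of the brain, had log2 differences of -0.06 with a standard error of 0.29 and 0.04 with a standard error of 0.30. Chrna7, the homomeric receptor gene, had -0.12 with a standard error of 0.29. Chrna10 was at 3.29 ± 0.01 with vehicle and 3.92 ± 0.03 with clothianidin (SD, n = 2 each), a level in the lowest range of the arrays. The log2 difference was -0.50 for Chrna3, -0.43 for Chrnd, -0.39 for Chrna6, -0.35 for Chrnb1, -0.30 for Chrng and 0.17 for Chrne. It was -0.15 for Chrnb3, -0.14 for Chrna1, -0.08 for Chrnb4, -0.08 for Chrna5, 0.03 for Chrna2 and 0.01 for Chrna9. Of 12 other cholinergic genes 4 were higher and 8 lower (camera adjusted p = 0.793), and the choline transporter gene Slc5a7 was at 3.66 ± 0.23 and 4.07 ± 0.28 (SD, n = 2 each).

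Immediate early genes, which neurons switch on within minutes of activity, did not shift as a list, with 18 of 39 higher and 21 lower (camera adjusted p = 0.419). Npas4 was at 8.29 and 6.54 with vehicle and 3.78 and 4.37 with clothianidin, and it was the only gene of any list to pass limma adjusted over the list alone (adjusted p = 0.00962), while over all genes its limma adjusted p was 0.997. The phosphatase gene Dusp1 was at 14.92 ± 0.00 with vehicle and 14.05 ± 0.05 with clothianidin, and Fos at 8.71 ± 0.29 and 7.84 ± 0.48 (SD, n = 2 each). Klf4 went the other way, at 4.43 ± 0.21 and 5.14 ± 0.57 (SD, n = 2 each).

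The list of calcium handling and Purkinje long-term depression genes, the signalling chain that weakens parallel fibre synapses during motor learning, rose with clothianidin, with 33 of 42 genes higher and a median log2 difference of 0.25 (camera adjusted p = 0.000117). This call was lost at adjusted p = 0.874 with an estimated correlation, a test that rests on 2 residual degrees of freedom. The plasma membrane calcium pump gene Atp2b1 was at 10.28 ± 0.13 with vehicle and 11.13 ± 0.01 with clothianidin, and the T-type calcium channel gene Cacna1g at 12.12 ± 0.39 and 13.11 ± 0.40 (SD, n = 2 each). Cacna1b, an N-type channel gene, and the neuronal nitric oxide synthase gene Nos1 had log2 differences of 0.92 and 0.82. No member passed limma over all genes or adjusted over the list alone. The median deviation of the list from its mean over the arrays was -0.07 and -0.22 on the vehicle arrays, 0.33 on clothianidin replicate 6 and -0.10 on clothianidin replicate 7. Without clothianidin replicate 6 the median difference was 0.09, and without clothianidin replicate 7 it was 0.4325.

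Synaptic vesicle and release genes rose as a list, with 27 of 36 higher and a median of 0.18 (camera adjusted p = 0.0194), lost at adjusted p = 0.874 with an estimated correlation. Shank2, a postsynaptic scaffold gene, had a log2 difference of 1.11, the release priming gene Unc13c 0.86 and the active zone gene Pclo 0.82, while the vesicular glutamate transporter gene Slc17a6 had -1.02. Without clothianidin replicate 6 the median of the synaptic list turned to -0.06. Without vehicle replicate 9 its camera adjusted p was 0.263. After a further quantile normalization its median was 0.08 and its camera adjusted p 0.197, and with the filters on level at the median and the 25th percentile the adjusted p was 0.130 and 0.0559.

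Markers of the 2 main neuron types of the cerebellum were higher by the median difference over each list. Purkinje cell markers rose with 15 of 20 higher and a median of 0.19 (camera adjusted p = 0.0194), lost at adjusted p = 0.874 with an estimated correlation. Calb1 and several other Purkinje markers also belong to the calcium handling list, so these 2 calls are not independent. The Purkinje list deviated by -0.16 and -0.15 on the vehicle arrays and by 0.12 and 0.09 on the clothianidin arrays. Calb1 was at 15.74 ± 0.01 and 16.41 ± 0.15, Pcp2 at 16.25 ± 0.21 and 16.93 ± 0.35, and Pcp4 at 16.25 ± 0.14 and 16.93 ± 0.54 (SD, n = 2 each). Bcl11a had a log2 difference of 0.60. Granule cell markers rose with 12 of 18 higher and a median of 0.26 (camera adjusted p = 0.0386), lost at adjusted p = 0.874 with an estimated correlation, and the transcription factor genes Zic2, Zic1 and Pax6 had log2 differences of 0.97, 0.57 and 0.42 and the cadherin gene Fat2 0.82. Without clothianidin replicate 6 Zic1 was at 0.16. The granule list deviated by -0.03 and -0.19 on vehicle replicates 7 and 9. It deviated by 0.29 and -0.10 on clothianidin replicates 6 and 7, so the groups overlapped. The granule median was 0.02 without clothianidin replicate 6 (camera adjusted p = 0.885), and 0.18 without vehicle replicate 9 (camera adjusted p = 0.264). The Purkinje call ended without vehicle replicate 7, vehicle replicate 9 or clothianidin replicate 6, though the median did not shrink. It was 0.275, 0.3175 and 0.21 in these fits, against 0.19 with all arrays. After quantile normalization the camera adjusted p was 0.197 for Purkinje and 0.324 for granule cell markers, and the granule call also ended on ranks with adjusted p = 0.0540. With the filters on level at the median and the 25th percentile the camera adjusted p was 0.104 and 0.0839 for Purkinje and 0.256 and 0.115 for granule cell markers.

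Heat shock and unfolded protein response genes rose with 22 of 30 higher and a median of 0.23 (camera adjusted p = 0.0194), lost at adjusted p = 0.874 with an estimated correlation. The co-chaperone gene Bag3 was at 8.0 ± 0.08 with vehicle and 8.69 ± 0.07 with clothianidin, and the stress transcription factor gene Ddit3 at 8.79 ± 0.06 and 9.34 ± 0.01 (SD, n = 2 each). Another probe set for Ddit3 had a small difference of the opposite sign. The list deviated by -0.02 and -0.23 on the vehicle arrays and by 0.11 and 0.05 on the clothianidin arrays. Sdf2l1 had a log2 difference of 0.47 and Sesn2 one of -0.59. The heat shock call ended without vehicle replicate 9, clothianidin replicate 6 or clothianidin replicate 7, with camera adjusted p of 0.264, 0.0845 and 0.0842, after quantile normalization with 0.197, and with the filters on level at the median and the 25th percentile with 0.125 and 0.10.

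Oligodendrocyte markers fell as a list, with 16 of 17 lower and a median of -0.19 (camera adjusted p = 0.0194), lost at adjusted p = 0.874 with an estimated correlation. The myelin genes Cnp, Mal and Mog had log2 differences of -0.73, -0.50 and -0.68, and the fatty acid hydroxylase gene Fa2h -0.54. Mog was -0.15 without vehicle replicate 7 and -1.20 without vehicle replicate 9. The median of the list was -0.40 without vehicle replicate 9. The deviation of the list was 0.28 on vehicle replicate 7 and -0.05, -0.10 and -0.14 on the other arrays, and without vehicle replicate 7 the median was -0.04 (camera adjusted p = 0.381). The call also ended without clothianidin replicate 6 or clothianidin replicate 7, with camera adjusted p of 0.0845 and 0.0647.

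**Figure D2:**
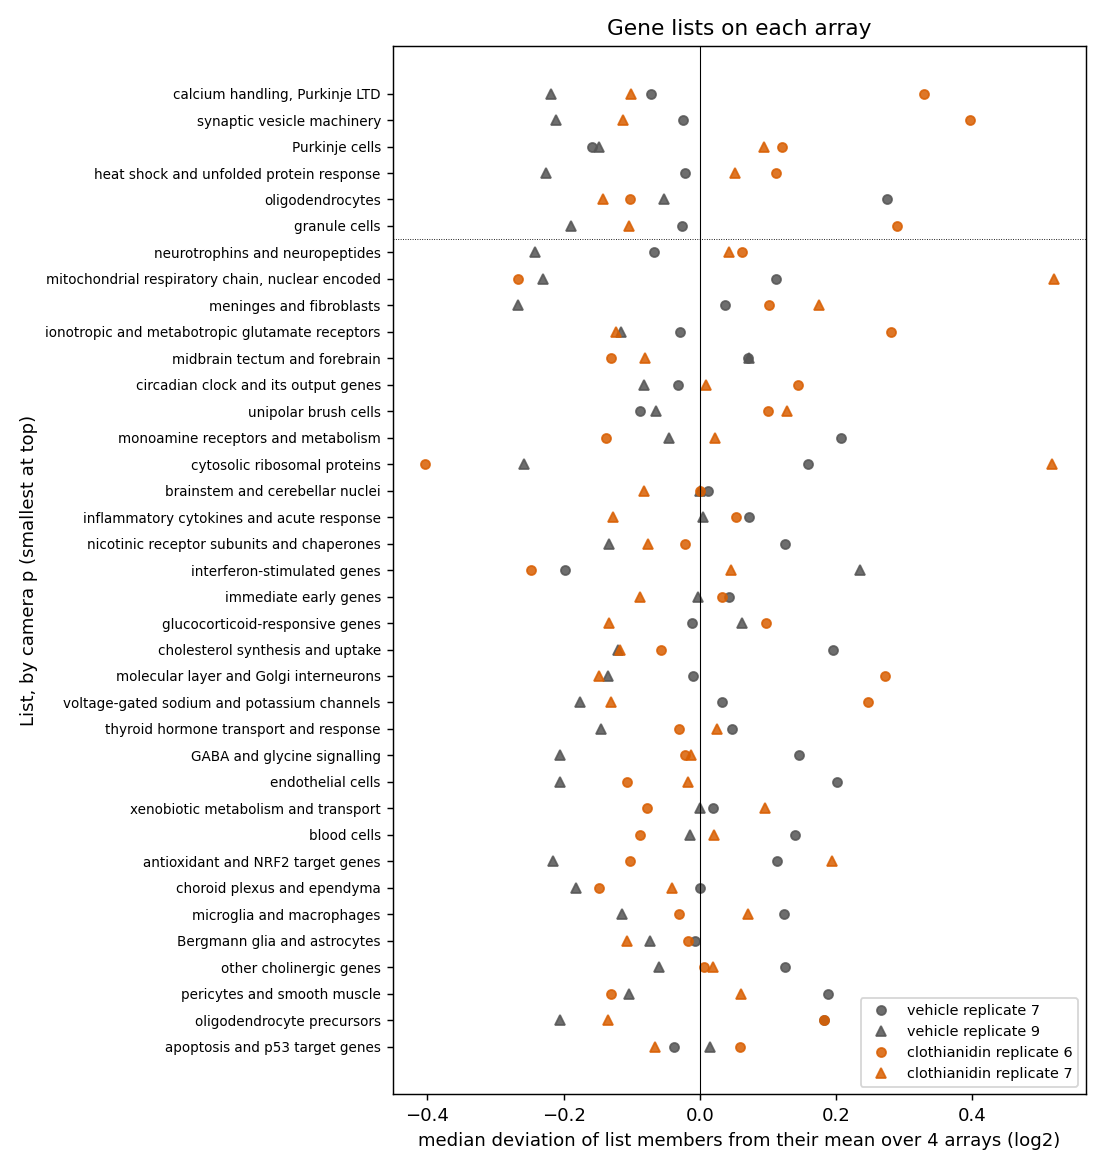
Median deviation of each list's members from their own mean over the 4 arrays, on the log2 scale, for the 37 lists tested, ordered by camera p with the smallest at the top. Grey points are vehicle and orange points clothianidin arrays, and the 6 lists above the dotted line passed camera with its preset correlation. The calcium handling list stands at 0.33 on clothianidin replicate 6 and at -0.10 on replicate 7.

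The remaining lists did not pass camera, and 10 lists in all had adjusted p under 0.1. Neurotrophin and neuropeptide genes had 16 of 23 higher (camera adjusted p = 0.0621), with a log2 difference of 0.97 for the neurotrophin-3 receptor gene Ntrk3 and 1.24 for the substance P precursor gene Tac1. With 1 array left out, Tac1 ranged from 0.58 without clothianidin replicate 7 and 0.65 without vehicle replicate 9 to 1.89 without clothianidin replicate 6. Nuclear-encoded respiratory chain genes had 40 of 62 higher (camera adjusted p = 0.0621), with Cox7b at 1.0 and Ndufb3 at 0.87, and the list deviated by -0.27 on clothianidin replicate 6 and by 0.52 on clothianidin replicate 7. Markers of meninges and fibroblasts had 13 of 18 higher (camera adjusted p = 0.0621), with Islr at 0.67. Glutamate receptor genes had 19 of 28 higher (camera adjusted p = 0.0645), with Grid1 at 0.98, Grin3b at 0.83 and Grm5 at -0.95.

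Among the remaining cell type markers, the camera adjusted p was 0.142 for midbrain tectum and forebrain, with 14 of 17 lower, and 0.271 for brainstem and cerebellar nuclei, with 13 of 19 lower, Th at 0.93 and Slc17a6 at -1.02. Tcf7l2 of the midbrain and forebrain list was at -1.17, but at -0.17 without vehicle replicate 7 and -2.18 without vehicle replicate 9. The brainstem list was the only one that passed fry (adjusted p = 0.0481). Fry asks whether a list taken by itself moves on balance in one direction, while camera sets it against the other genes. The brainstem list deviated by 0.01 and 0 on the vehicle arrays and by 0 and -0.08 on the clothianidin arrays. By this measure the groups were not apart. The camera adjusted p was 0.206 for unipolar brush cells with Eomes at 0.87, 0.419 for molecular layer and Golgi interneurons with Kit at 0.60, and 0.793 for Bergmann glia and astrocytes with Hopx at 0.52. Eomes was at 0.28 without vehicle replicate 7 and at 1.45 without vehicle replicate 9. It was 0.855 for oligodendrocyte precursors with Enpp6 at -1.01, a list whose median of 0.05 and mean of -0.02 differed in sign. It was 0.793 for microglia and macrophages with Aif1 at 0.93, 0.646 for endothelial cells with Esam at -0.39, 0.816 for pericytes and smooth muscle with Anpep at 0.48, and 0.720 for blood cells with Slc4a1 at -0.54. Markers of choroid plexus and ependyma had 8 of 18 higher (camera adjusted p = 0.731), with a median of -0.07 and a mean of 0.31 that differed in sign, and Folr1, Ecrg4 and Kcnj13 had log2 differences of 0.88, 0.97 and 1.09, which were 0.47, 0.30 and 0.11 without clothianidin replicate 7.

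Among the remaining pathways, the camera adjusted p was 0.206 for circadian clock genes with Nr1d1 at 0.61, 0.210 for monoamine genes with Maob at -0.58, 0.215 for cytosolic ribosomal proteins with Rpl6 at 0.73, and 0.326 for inflammatory genes with Nos2 at -0.86 and Il18 at 0.67. It was 0.337 for interferon-stimulated genes with Oas1a at -0.81 and B2m at 0.92, 0.419 for glucocorticoid-responsive genes with Angptl4 at -0.68, and 0.419 for cholesterol synthesis with Lss at -0.49. It was 0.460 for sodium and potassium channels with Scn3a at -0.67, 0.480 for thyroid hormone transport and response, which holds Ttr, and 0.548 for GABA and glycine signalling with the chloride exporter gene Slc12a5 at 0.90. It was 0.699 for xenobiotic metabolism with the glutathione transferase gene Gstp1 at 1.02, 0.731 for antioxidant genes with Gss at -0.76 and Cat at -0.62, and 0.909 for apoptosis and p53 targets with Fas at 0.76, a list whose median of 0.07 and mean just below 0 differed in sign.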

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

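The test of lists after quantile normalization among genes at or above the median level was chosen after the result was seen, and the other alternatives were planned. No paired analysis was possible because the groups share only replicate number 7. The count of genes called by limma stayed at 0 under centring, quantile normalization, both level filters, 1 probe set per gene, other priors and an adjusted p of 0.1. A linear model without moderation called 8, each with no spread within either group because values are rounded. Leaving out 1 array gave 0 to 1 calls, the 1 being Ttr without clothianidin replicate 6, where 1 array stands for its group and is assumed to vary like the vehicle arrays. At an unadjusted limma p under 0.05, the count of 940 became 1276 without vehicle replicate 7, 851 without vehicle replicate 9, 576 without clothianidin replicate 6 and 970 without clothianidin replicate 7. The count of probe sets at least 1.5-fold apart without overlap was 1689, against 924 among those at or above the median level (fewer probe sets tested), 5348 at 1.2-fold, 206 at 2-fold, and 2922 to 4120 with 1 array left out, where fewer arrays make overlap rarer. The count of lists was 6, against 2 after quantile normalization, 2 with the median filter, 2 with the 25th percentile filter, 2 with quantile normalization and the median filter together (calcium handling and oligodendrocytes in each of these 4 settings), 10 at adjusted p under 0.1, 0 with an estimated correlation, 1 with fry, and 2 to 9 with 1 array left out. The 2 lists without clothianidin replicate 6 included 0 of the 6. The cause of the other differences was not tested. Of 721 gene values under alternatives for 103 genes, 703 kept direction and side of the threshold, 17 turned and 1, Ttr, gained a call. Side of the threshold says little here, since 64 of the 103 genes moved by over 1.5 times without 1 array. Chrnb2 turned to -0.065 after quantile normalization. With 1 array left out at a time, the log2 difference ranged from -0.19 to 0.27 for Chrnb2, -1.115 to 0.125 for Chrna3, -0.29 to 0.17 for Chrna4, -0.33 to 0.10 for Chrna7, -0.785 to 0.015 for Chrna6, -0.52 to 0.22 for Chrnb3 and -0.375 to 0.215 for Chrnb4. It ranged from -0.345 to 0.365 for Chrna9, -0.315 to 0.545 for Uty, -0.355 to 0.085 for Chrna1, -0.415 to 0.255 for Chrna5 and -0.24 to 0.30 for Chrna2. The synaptic list ranged from -0.06, without clothianidin replicate 6, to 0.5175. Signal over background is unknown for these arrays.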

Other observations

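Tests on quantile-normalized parts of the called lists, on gene length, on choroid plexus markers, on the immediate early list without Npas4 and on gene families were chosen after the result was seen. Among the 37 lists tested, the median deviations of ribosomal protein and respiratory chain transcripts lay furthest apart between the 2 clothianidin samples. Cytosolic ribosomal protein genes deviated from their means by -0.40 on clothianidin replicate 6 and 0.52 on clothianidin replicate 7, and by 0.16 and -0.26 on vehicle replicates 7 and 9. Glutamate receptor and synaptic vesicle genes lay the other way, at 0.28 and 0.40 on clothianidin replicate 6 and -0.12 and -0.11 on clothianidin replicate 7. Gene length ran along this difference: among the 992 shortest of the genes at or above the median level the median deviation was -0.09 on clothianidin replicate 6 and 0.16 on clothianidin replicate 7, and among the 992 longest it was 0.23 and -0.10.

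Histone genes, looked at with 6 other families after H4c3 and H1f3 were seen, were lower in 61 of 82 cases with a median log2 difference of -0.16 (-0.18 after quantile normalization, camera unadjusted p = 0.000173). H4c3 and H1f3 chose this family, so that p is no independent evidence. Olfactory and vomeronasal receptor genes, mostly near the bottom of the intensity range, were lower in 974 of 1412 cases. Their median was -0.15, and -0.07 after quantile normalization. Their camera unadjusted p of 1.17e-06 was smaller than that of the histone genes. Of the Y-linked genes, Eif2s3y and Kdm5d had log2 differences of 1.41 and 0.98, while Uty was at 11.19 and 10.33 with vehicle and 10.91 and 10.84 with clothianidin.

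The first pattern was the shift of 6 lists with camera. A technical hypothesis set down beforehand was that compression of an array's range made bright genes look higher with clothianidin, since the interquartile range was 4.88 on vehicle replicate 9 and 5.14 to 5.30 on the others, and it predicted that most of the lists would not pass after quantile normalization; 2 of 6 passed, as it predicted. Taken apart afterwards, the 2 that passed were calcium handling and oligodendrocytes. The calcium median was 0.25 before and 0.19 after (camera adjusted p = 0.0159), and 0.15 with the median filter added (camera adjusted p = 0.0407). This argues against compression as the whole cause of the calcium call at the preset correlation. The oligodendrocyte median was -0.19 before and -0.25 after (camera adjusted p = 0.00105). Compression as stated makes bright genes look higher, so it did not predict a fall, and the passing of this list was no test of it. For the others, of which 0 passed, compression stays open as a part. The synaptic and granule medians went from 0.18 to 0.08 and 0.26 to 0.13. The Purkinje and heat shock medians went from 0.19 to 0.14 and 0.23 to 0.19. No error was computed for these moves, so their sizes do not tell how large the part of compression was in each list. The calcium list also lay at the 99.75th percentile of random lists matched on level and genomic length, outside the central 95%. Genes were drawn independently for the random lists, while the calcium list had an estimated correlation of 0.35. A list whose genes move together can lie outside for that reason alone, so this percentile does not decide on level and gene length. By this measure the synaptic list at 93.69 and the Purkinje list at 91.61 lay within the central 95%, so level and length stay open for those. The granule list at 97.69 lay just outside, but its call ended after quantile normalization, so level stays open for it too. The heat shock list at 99.12 and the oligodendrocyte list at 0.28 also lay outside the central 95%. The same limit holds for them, and the heat shock call ended after quantile normalization. Genes that move as blocks from array to array remain a candidate explanation, since the 4 arrays allow 3 splits, too few for a share under 0.05, and the real split called 6 lists where the highest other split, vehicle replicate 7 with clothianidin replicate 6 against the rest, called 9, including 3 of the same 6, with calcium handling among them at a median of 0.27 (adjusted p = 0.00950). The smallest camera adjusted p of any list was 0.000117 in the real split, 2.208e-06 in that other split and 8.995e-23 in the remaining one. An effect of clothianidin on these transcripts stays open beside movement in blocks and was not tested separately.

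The second pattern was Ttr, which stood 8.04 above the mean of the other arrays on clothianidin replicate 7. Choroid plexus, the tissue with abundant transthyretin that borders the cerebellum at the fourth ventricle, could have been carried along in that sample. Of 17 other choroid plexus and ependyma markers, 3 (Folr1, Kcnj13 and Ecrg4) lay over 0.5 above all other arrays there, which is 17.6%, against 2.93% of 19487 other genes (Fisher's exact test, one-sided, p = 0.0126). On that array Folr1, Kcnj13 and Ecrg4 were at 6.05, 8.92 and 6.14, against 5.24, 6.97 and 4.80 on clothianidin replicate 6, and the remaining markers did not stand out by this measure. An effect of clothianidin on Ttr in the cerebellum itself stays open and was not tested, with replicate 6 at 6.38.

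The third pattern was Npas4, which was low on both clothianidin arrays. Its moderated t had a size of 6.26, and the highest in the other 2 splits was 6.95, with splits too few for a share under 0.05. In the list of immediate early genes without Npas4, 20 genes were lower and 18 higher, with a mean of -0.02 (95% interval over genes -0.17 to 0.12, camera unadjusted p = 0.507). So the list as a whole was not lower on these arrays. The interval takes genes as independent and does not measure the spread between samples. A fall of some members, such as Dusp1 and Fos, stays open. The time between the rotarod run and dissection, handling and clothianidin itself may each move an activity-dependent gene such as Npas4, and none of these was tested.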
